A study of Homo sapiens with 4 samples.

How the data were processed

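RNA of 4 cultures was hybridised to Affymetrix HG-U133 Plus 2.0 arrays, on which a gene is read by probe sets, small groups of oligonucleotides, in 1 colour. The deposited values are intensities on a linear scale, 1 per probe set and array, with no detection calls. Per the submitters' processing notes, MAS5 was used. Its version, its role and the scaling target are not given in the sources used here, nor is the background correction. The deposited columns had medians of 6.07 for CL1-0 with control vector, 6.23 for CL1-0 labelled AK4 vector, 15.6 for CL1-5 with non-silencing shRNA and 15.3 for CL1-5 with AK4 shRNA. Their trimmed means, with 2% removed at each end, were 37.5, 36.8, 68.5 and 69.4 in the same order, so as deposited the arrays did not share a trimmed mean. Many values were tied, with 41656 to 48513 distinct values among the 54675 of an array. Whether the columns are scaled MAS5 signals or another summary of the probes is open. No value was negative, and the values were not on a log scale.

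Each array was rescaled to a common trimmed mean with 2% removed at each end, over all probe sets except the 62 control probe sets. A floor was then set at the 40th percentile of all scaled values of the 4 arrays, a signal of 6.93 or 2.79 on the log2 scale. Values under the floor were set to it before log2 was taken. The array table holds 54675 probe sets. Of these, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 had no listed gene, the control probe sets included. Symbols were updated through the gene identifier for 99.9% of the named probe sets. These probe sets stood for 19775 genes. A gene was read from its probe set with 1 gene symbol and the highest mean log2 level over the 4 arrays. More than 1 probe set was present for 53.2% of genes.

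The groups came from the genotype labels, with 1 array in each of the 4 groups. No test and no p-value was possible, and the number of arrays limits the precision of every value. In each of 3 comparisons a log2 ratio was computed per gene. A gene counted as measured where at least 1 of the 2 arrays lay above the floor, and as higher or lower where the ratio was at least 2-fold. For a gene above the floor on 1 array only, the dimmer value is the floor, so the ratio is a lower bound for the probe set used and this scaling, not for the gene. The scatter within an array was described by the pooled SD of the log2 ratio between probe sets of the same gene, which was 0.41 for the vector comparison, 0.22 for the shRNA comparison and 0.85 for the comparison of the controls. This SD includes real differences between transcripts and is not a replicate error.

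In all, 37 gene lists with 985 distinct members were fixed before the data were examined. Of these lists, 7 held cell type markers, those of alveolar type II cells among them. Of the members, 895 had a probe set with 1 gene symbol. The median log2 ratio of the measured members of each list was set among 10000 random lists of the same size, matched on mean expression over 20 level bins. A list was described as outside the range where its median lay below the 2.5th or above the 97.5th percentile. This describes these arrays and is not a test across conditions. By construction 1.85 of the 37 lists would lie outside in a comparison by chance if list members varied as independently as randomly drawn genes. Genes that are regulated together do not, so more lists can lie outside by chance. The lists are not independent of each other either. For calls shared by both lines, the observed count was set beside the product of both list lengths divided by the number of genes measured in both comparisons.

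The named genes were chosen by a rule fixed in advance. It took AK4 and ATF3, and per comparison the 10 highest and 10 lowest genes above the floor on both arrays whose other measured probe sets all moved the same way. It also took the 5 genes with the largest smaller ratio in each joint direction over both lines, and up to 4 members of each described list that passed the 2-fold rule, or the 2 largest where none passed. Y-linked genes and XIST were left out of the naming. Genes named outside this rule are marked as such where they appear.

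The procedure was tested on simulated data, on 19775 genes. The scatter added was the pooled SD between probe sets of a gene given above, the same at every signal level. It holds no variation between cultures and no larger scatter of dim signals. The counts of genes called below follow from that SD and are not error rates of these arrays. In the vector comparison it recovered 82 of 100 genes changed by 1.5 on the log2 scale and called 182 of 14623 unchanged genes. In the shRNA comparison it recovered 86 of 100 such genes and called 0 of 15157 unchanged genes. In the comparison of the controls it recovered 73 of 100 and called 3229 of 15534 unchanged genes. If the scatter of these arrays were as large as that SD, single calls there would be weak. Random lists of 30 genes lay outside the range in 5.5%, 3.5% and 3.0% of draws for the 3 comparisons. These lists were drawn at random with independent scatter, so the rates follow from the construction. They do not cover lists of genes that are regulated together. Lists of 30 genes shifted by 0.3 were found above the range in 94, 100 and 40.5% of draws.

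Alternatives fixed in advance were quantile normalization, no rescaling, loess of the ratio on the level within a comparison (span 0.4), a floor at the 20th or 60th percentile, no floor, a threshold of 3-fold, the mean of all probe sets of a gene, and leaving out probe sets whose identifier ends in _x_at or _s_at, which can bind several transcripts. A threshold of 1.5-fold was added after the data had been seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.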

Results

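Gene expression was measured in CL1-0 and CL1-5, human lung adenocarcinoma cell lines. CL1-5 is known as a more invasive subline selected from CL1-0. AK4 is a mitochondrial adenylate kinase, an enzyme that transfers phosphate groups between nucleotides. CL1-0 cells carried a control vector or an AK4 vector, and CL1-5 cells carried a non-silencing shRNA or an shRNA against AK4. Each of these 4 groups was 1 array, so no value below has a replicate error or a p-value. After scaling, 56.6% of probe sets lay above the floor on the CL1-0 control vector array, 57.6% on the CL1-0 array labelled AK4 vector, 63.4% on the CL1-5 non-silencing array and 62.4% on the CL1-5 AK4 shRNA array. Spearman's rho across probe sets, which are not independent replicates, was 0.966 for the pair of CL1-0 arrays and 0.990 for the pair of CL1-5 arrays. Between the lines it lay from 0.862 to 0.874.

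The 4 AK4 probe sets were read first, since they check the labels. In CL1-5 all of them were lower with AK4 shRNA, with log2 ratios of -0.88 for 204347_at, -1.25 for 204348_s_at, -0.91 for 225342_at and -1.12 for 230630_at, or between 41.9% and 54.4% of the non-silencing array. In CL1-0 none was higher on the array labelled AK4 vector. Their log2 ratios there were -0.13, -0.05, -0.25 and -0.09 in the same order. The positions of these probe sets against the vector insert are not given in the sources used here, and a probe set in the 3' untranslated region would not see a vector that carries the coding sequence alone. The CL1-0 label was therefore neither borne out nor contradicted by the AK4 signal, and every direction below drawn from that array rests on the label. AK4 itself was brighter in CL1-5 than in CL1-0. Between the control arrays the 4 probe sets were higher in CL1-5 by 2.63, 3.20, 2.71 and 3.16 on the log2 scale.

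ATF3, a stress-induced transcription factor and the gene this study is known for, was read by 3 probe sets. For the brightest, 202672_s_at, the scaled signal was 563 on the CL1-0 control array and 266 on the array labelled AK4 vector, a log2 ratio of -1.08. In CL1-5 it was 11.3 with non-silencing shRNA and 23.8 with AK4 shRNA, a log2 ratio of 1.08 close to the floor of 6.93. Probe set 1554980_a_at gave -0.87 in CL1-0 and 0.29 in CL1-5, and 1554420_at gave -0.35 and 0.04. All 3 thus had a lower signal on the array labelled AK4 vector and a higher one with AK4 shRNA, but only 202672_s_at passed 2-fold. On the CL1-5 non-silencing array 202672_s_at was dimmer than 1554980_a_at, at 11.3 against 17.4.

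**Figure D1:**
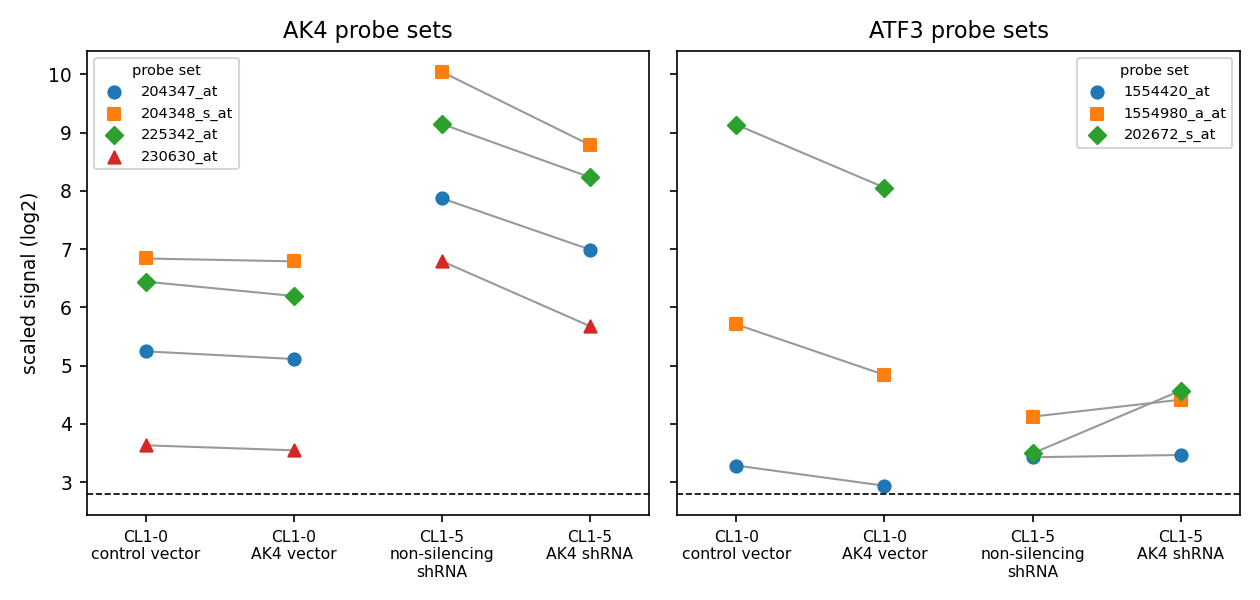
Scaled signal (log2) of each of the 4 AK4 and 3 ATF3 probe sets on the 4 arrays, 1 point per probe set and array, with grey lines joining the arrays of a line and a dashed line at the floor of 2.79. AK4 was lower with AK4 shRNA in CL1-5 and flat in CL1-0, and the brightest ATF3 probe set moved from 563 to 266 in CL1-0 and from 11.3 to 23.8 in CL1-5 on the linear scale.

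The comparison in CL1-0 asked which genes differ when AK4 is overexpressed. Mitosis genes stood highest on the array labelled AK4 vector. Of 36 measured members of this list, 16 were at least 2-fold higher, 0 were at least 2-fold lower and 35 had a ratio above 0. The list's median log2 ratio was 0.93, against a range of -0.12 to 0.26 for random lists. The kinase NEK2 was higher by 1.90, the kinesin KIF20A by 1.88, the spindle protein DLGAP5 by 1.83 and cyclin A2 (CCNA2) by 1.68. Outside the list lay SPC25, NUF2 and NDC80, subunits of the kinetochore complex that binds spindle microtubules. They were among the 10 highest genes under the naming rule, with log2 ratios of 2.39, 2.17 and 1.98. Immediate early genes, which respond within minutes to growth factors and stress, were lower on the same array. Of 26 measured members, 5 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.43 against a range of -0.13 to 0.29. NR4A3, an orphan nuclear receptor, was lower at -2.53, FOSL1 and FOSL2, subunits of the AP-1 transcription factor, at -2.25 and -1.55, and EGR3 at -1.71.

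Over all 14695 genes measured in that comparison, 472 were at least 2-fold higher and 171 at least 2-fold lower on the array labelled AK4 vector. The share of higher genes among them was 73.4%, and 62.7% after loess. The highest and lowest genes given here are those under the naming rule. The highest besides the kinetochore genes were C7orf57 at 2.63, NIPSNAP3A at 2.14, SH3BGRL at 2.05, the endoplasmic reticulum peptidase ERMP1 at 2.03, the splicing regulator RBM4 at 2.01, WDR17 at 2.01 and the scaffold protein IQGAP2 at 1.99. The lowest besides NR4A3 and FOSL1 were the transmembrane protein TMEFF2 at -3.43, ATN1 at -2.40, cyclin D2 (CCND2) at -2.24, DNMBP at -1.89, the antisense RNA MIF-AS1 at -1.87, the linker histone H1-2 at -1.86, the ephrin ligand EFNB2 at -1.86 and PPP1R15A, a phosphatase subunit of the stress response, at -1.80. H1-2 has close relatives in sequence, and its value is uncertain. With the mean of all probe sets, TMEFF2 was at -0.98, DNMBP at -0.98, NR4A3 at -0.93, ATN1 at -1.55, ERMP1 at 1.34 and IQGAP2 at 0.91, and with the floor at the 60th percentile EFNB2 was at -0.77, C7orf57 at 1.68 and WDR17 at 0.77.

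Genes of energy metabolism had medians above the random range in CL1-0. The 44 measured subunits of oxidative phosphorylation had a median log2 ratio of 0.27, or 0.15 with the mean of all probe sets, with 33 above 0 and 1 at least 2-fold higher. That member, NDUFS7 of complex I, was at 1.04 but at -0.36 when probe sets ending in _x_at or _s_at were left out. The 25 measured members of the tricarboxylic acid cycle list, which also holds enzymes next to the cycle, had a median of 0.30 with 0 past 2-fold. Their largest ratios were those of the succinate-CoA ligase subunits SUCLG2 (0.98) and SUCLA2 (0.80). The 25 genes of glycolysis and lactate export had a median of 0.31, with 15 above 0. PDK3, a kinase that inhibits pyruvate dehydrogenase, was higher by 1.26 and glucose-6-phosphate isomerase (GPI) by 1.22. PDK3 was at 0.52 with the mean of all probe sets.

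Below the random range in CL1-0 lay 3 further lists. Receptor tyrosine kinases and their ligands had a median of -0.25 over 29 genes, 3 of them at least 2-fold lower and 2 at least 2-fold higher. The receptor MET was at -1.13, the ligands NRG1 and FGF2 were at -1.39 and -1.07, and the receptor FGFR3 was at 1.23. The list's median was -0.12 with the mean of all probe sets and -0.16 with no floor. With the mean of all probe sets these 4 ratios were -0.24, -0.41, -0.43 and 0.55 in the same order. The list of unfolded protein response chaperones, which also holds regulators of that response, had a median of -0.27 over 20 genes, with 0 past 2-fold. The largest ratios were those of the regulators ATF6 (-0.77) and XBP1 (-0.74). ATF6 reversed to 0.15 with the mean of all probe sets and XBP1 was then at -0.39. NF-kB targets and inflammatory cytokines had a median of -0.15 over 17 genes, with 0 past 2-fold and the largest ratios at RELB (-0.92) and LIF (-0.92). The chaperone and glycolysis lists moved inside the random range when probe sets ending in _x_at or _s_at were left out, and the NF-kB list did so under 3 of 8 alternatives.

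The CL1-0 arrays also differed in their controls. The ratio of 3' to 5' signal of beta-actin, which grows with RNA degradation, was 6.04 on the control vector array and 6.54 on the array labelled AK4 vector. The BioB hybridisation controls had a scaled signal of 761 on the former and 296 on the latter. Among called genes with several probe sets above the floor on both arrays, 220 of 301, or 73.1%, had all of them on the same side. Over all genes with several such probe sets the share was 50.9%.

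The comparison in CL1-5 asked which genes differ when AK4 is silenced. Interferon-stimulated genes, which act in antiviral defence, were higher with AK4 shRNA. All 37 measured members had a ratio above 0, and 7 were at least 2-fold higher. The list's median was 0.58 against a random range of -0.06 to 0.09. RSAD2, an antiviral enzyme, was higher by 1.39, IFIT2 by 1.34, IFI44 by 1.22 and the RNA sensor IFIH1 by 1.14. Also among the 10 highest genes under the naming rule were the chemokines CXCL11 (1.31) and CCL5 (1.23) and the transcription factor HIVEP1 (1.22). So were the mitochondrial nucleotide kinase CMPK2 (1.17), the oligoadenylate synthetase OAS2 (1.11) and ATF3 (1.08). CXCL11 and CCL5 were the only 2 of 23 measured NF-kB targets and cytokines past 2-fold, and that list's median was 0.28 against a range of -0.10 to 0.10, and 0.074 with the mean of all probe sets.

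In all, 14 of 15335 measured genes were at least 2-fold higher with AK4 shRNA and 2 at least 2-fold lower. The lower genes were AK4 at -1.25 and EIF5A, a translation factor, at -1.09. The next lowest under the naming rule were TULP1 at -0.90, chromogranin A (CHGA) at -0.80, SV2B at -0.79 and the protease CTSH at -0.78. MARK2P21, FLJ30679 and IRAG1 followed, each at -0.76, with ALYREF, an mRNA export factor, at -0.76. Except for AK4, EIF5A and ALYREF, these genes had low signals, between 6.98 and 33.7 on either array, and with the floor at the 60th percentile TULP1, SV2B, CTSH and IRAG1 were at 0.00, CHGA at -0.18 and FLJ30679 at -0.05. Without probe sets ending in _x_at or _s_at, IFI44 was at 0.43 and CXCL11 at 0.00. With the floor at the 60th percentile, ATF3 was at 0.51, CXCL11 at 0.50 and HIVEP1 at 0.39. With the mean of all probe sets, IFIT2 was at 0.94, CXCL11 at 0.82, HIVEP1 at 0.73, OAS2 at 0.70, IFIH1 at 0.48, ATF3 at 0.47 and EIF5A at -0.93.

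Smaller shifts in CL1-5 lay outside the random range in 5 further lists, none with a member past 2-fold. Antigen presentation genes had a median of 0.13 over 18 genes, with PSMB8 of the immunoproteasome at 0.53 and the peptide-loading protein TAPBP at 0.49, or 0.05 with the mean of all probe sets. Epithelial junction and keratin genes had a median of 0.12 over 29 genes, with the desmosome proteins DSP at 0.53 and JUP at 0.48. Their median was 0.048 with the mean of all probe sets and 0.066 with no floor. Antioxidant enzymes had a median of -0.15 over 27 genes, with the metallothioneins MT1X at -0.52 and MT1G at -0.44, whose probe sets may be shared with near-identical family members and of which MT1G was at 0.00 without probe sets ending in _x_at or _s_at. Leukocyte markers had a median of -0.22 over 7 dim genes, and proteasome subunits had a median of -0.07 over 25 genes. Antioxidant enzymes had a median of -0.09 with the mean of all probe sets and moved inside the range under 1 of 8 alternatives, leukocyte markers under 3 and proteasome subunits under 4. Mitosis genes were inside the range in this comparison, with a median of 0.0047 over 36 genes. The beta-actin 3' to 5' ratio was 1.34 on the non-silencing array and 1.61 on the AK4 shRNA array, and the BioB signals were 104 and 96.9.

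**Figure D2:**
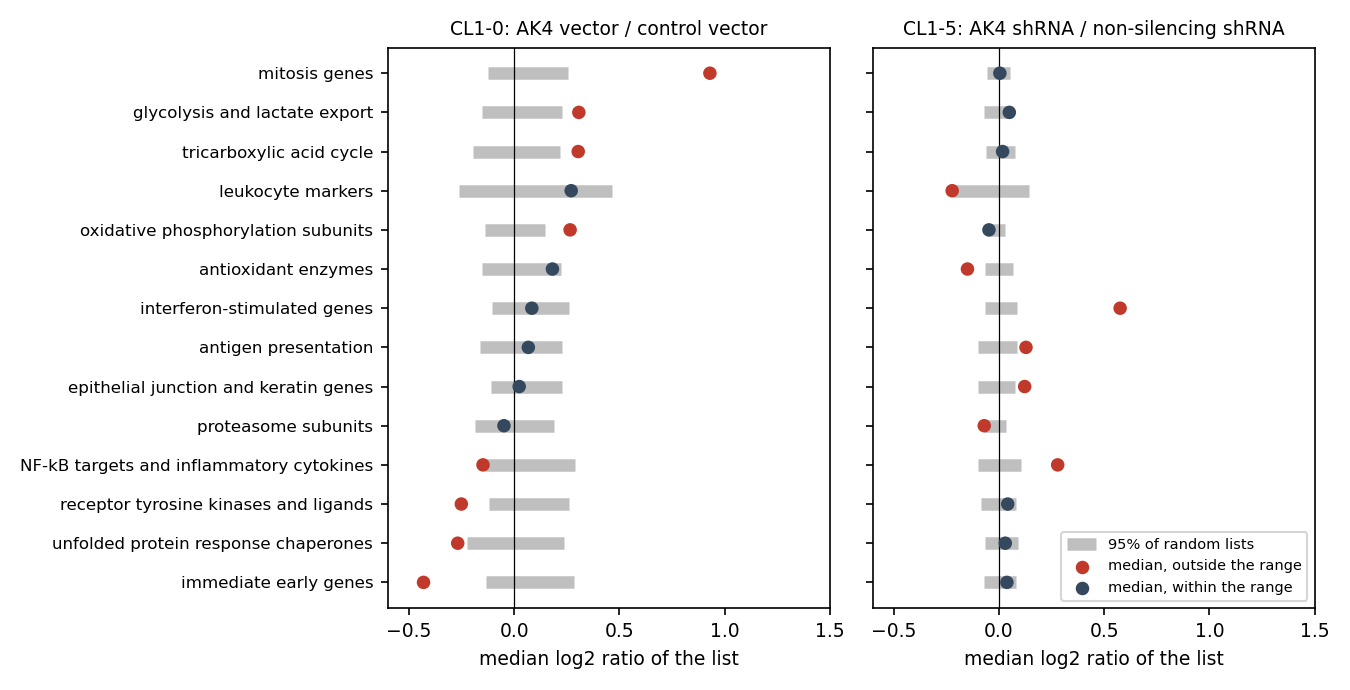
Median log2 ratio of each gene list outside the random range in at least 1 line, with the AK4 vector comparison in CL1-0 on the left and the AK4 shRNA comparison in CL1-5 on the right. Points are medians, red where outside, and grey bars span 95% of random lists. Mitosis genes stood at 0.93 in CL1-0 and interferon-stimulated genes at 0.58 in CL1-5.

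Genes that move with AK4 should be higher with the vector and lower with shRNA, or the mirror. Of 13794 genes measured in both comparisons, 0 were at least 2-fold higher on the array labelled AK4 vector and at least 2-fold lower with AK4 shRNA, where independent lists would share 0.063. In the mirror direction there was 1 gene, ATF3, where independent lists would share 0.115. ATF3 no longer passed 2-fold in both lines under quantile normalization, with the floor at the 60th percentile, with the mean of all probe sets or without probe sets ending in _x_at or _s_at, and its direction held under each. The naming rule, which leaves out genes whose probe sets disagree, ranked genes by the lesser of their 2 ratios in size. After ATF3 it gave, in the same direction, CCL5 (-0.72 in CL1-0 and 1.23 in CL1-5), SMIM14 (-0.79 and 0.57), the TGF-beta-responsive factor KLF10 (-1.21 and 0.56) and HIVEP2 (-0.76 and 0.52). Outside the rule, H4C8, whose value is uncertain, was at -1.79 and 0.66. Under the mean of all probe sets CCL5 was at -0.31 and HIVEP2 at -0.27 in CL1-0 and SMIM14 at 0.32 in CL1-5, and without probe sets ending in _x_at or _s_at HIVEP2 was at -0.08 in CL1-0. Under the naming rule, which leaves out genes whose probe sets disagree, the opposite pattern had its largest ratios at SPACDR (0.53 and -0.57), the GTPase RAB20 (0.67 and -0.53), the myogenic factor MYOD1 (0.56 and -0.52), LOC105376689 (0.51 and -0.70) and NRIP3 (0.51 and -0.58), none of which passed 2-fold in either line. Each of these 5 shrank by over 1.5 times in at least 1 line under some alternative. RAB20 reversed to 0.09 in CL1-5 with the mean of all probe sets, which ends the pattern. With the floor at the 60th percentile the CL1-0 ratio of SPACDR was 0.075 and those of MYOD1 and LOC105376689 were 0.00, and NRIP3 was at 0.19 and -0.25 without probe sets ending in _x_at or _s_at.

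Some genes had the same sign in both lines, against the opposite changes intended for AK4. CMPK2 was at least 2-fold higher in both, at 1.10 in CL1-0 and 1.17 in CL1-5, where independent lists would share 0.317 genes. IFIT1 (0.96 in both), BST2 (1.16 and 0.83) and the ubiquitin-like ligase HERC5 (0.79 and 0.91), all on the interferon-stimulated list, and MIDN (0.81 and 0.78) followed. The interferon-stimulated list as a whole was inside its random range in CL1-0, with a median of 0.084 and 1 of 29 members at least 2-fold higher. With the floor at the 60th percentile the CL1-0 ratio of CMPK2 was 0.08, those of BST2 were 0.00 in both lines and the CL1-5 ratio of C6orf52 was -0.33. MIDN was at 0.00 in both lines without probe sets ending in _x_at or _s_at. Lower in both were EIF5A (-0.97 and -1.09), C6orf52 (-0.76 and -0.72), the splicing factor HNRNPL (-0.89 and -0.68), the histone H3-3A (-1.22 and -0.63) and the transcription factor KLF5 (-1.31 and -0.54). H3-3A has a near-identical copy and its value is uncertain, at -0.55 in CL1-0 with the floor at the 60th percentile. KLF5 was at -0.36 in CL1-0 and 0.00 in CL1-5 without probe sets ending in _x_at or _s_at. Across genes, which are not independent replicates, the ratios of both comparisons had a Pearson r of 0.13 and a Spearman rho of 0.12, and 46.0% of genes had opposite signs.

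**Figure D3:**
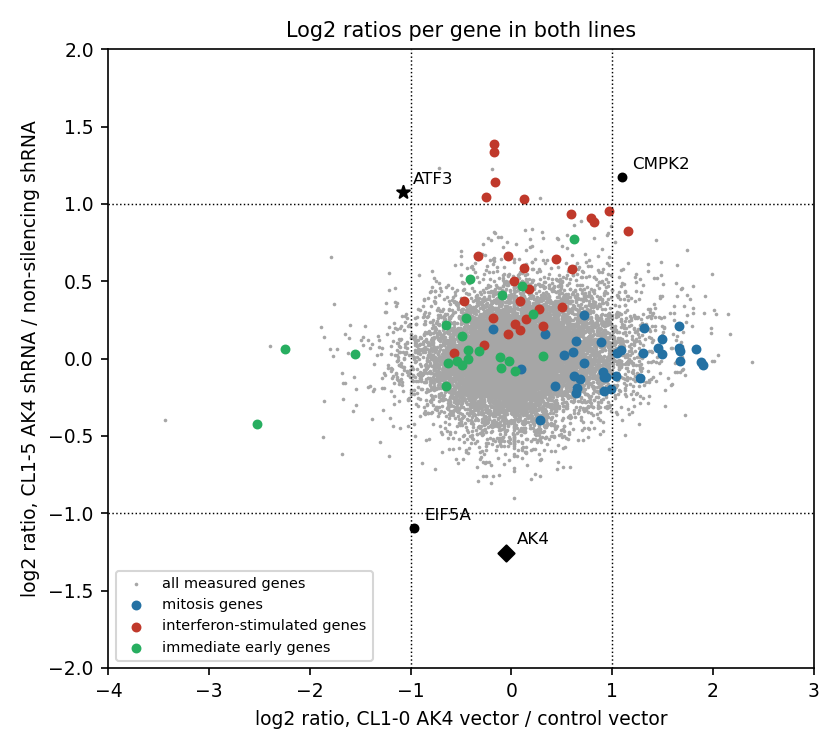
Log2 ratio of each gene measured in both comparisons, Y-linked genes left out, for AK4 vector over control vector in CL1-0 (x axis) against AK4 shRNA over non-silencing shRNA in CL1-5 (y axis), with dotted lines at 2-fold and immediate early genes in green. Mitosis genes (blue) spread along the x axis and interferon-stimulated genes (red) along the y axis, and ATF3 lies alone past both lines at upper left (-1.08 and 1.08).

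The control arrays of CL1-5 and CL1-0 were compared to describe the sublines in which AK4 was altered. Mitosis genes were higher in CL1-5, with 35 of 36 at least 2-fold higher and a median of 2.38 (random range -0.48 to 0.27). KIF20A was higher by 5.16, DLGAP5 by 4.96, the proliferation marker MKI67 by 4.09 and the kinase PLK1 by 3.43. DNA replication genes followed with a median of 1.20 and 23 of 40 at least 2-fold higher and 3 lower, among the former cyclins E2 (CCNE2, 3.38) and D1 (CCND1, 2.82), whereas CCND2 was lower at -6.63 and CDKN2A at -3.80. Targets of the integrated stress response, which amino acid shortage and related stresses induce, were lower in CL1-5. Of 34 measured members, 25 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -1.85 (random range -0.53 to 0.26). ATF3 was at -5.64, DDIT3 (CHOP) at -4.74, the cysteine-forming enzyme CTH at -3.88 and ALDH1L2 at -3.53. CCND2 and ALDH1L2 were above the floor on 1 array only, so the size of their ratios is set in part by the floor. With the mean of all probe sets, CCND2 was at -3.54, CDKN2A at -2.14, ATF3 at -2.36 and ALDH1L2 at -1.58. The other ATF3 probe sets gave -1.58 and 0.14. With no rescaling, the ratios of this comparison rose as a whole, though not by the same amount for every gene (median of all genes 0.83, from 0.13). The stress response list then had a median of -0.98 and stayed below its random range.

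Lists of genes of invasion and matrix contact had medians above 0 in CL1-5, with members on both sides. Mesenchymal genes had a median of 1.003, with 19 of 37 at least 2-fold higher and 4 lower. LOXL2 was higher by 6.87, the transcription factor SNAI2 by 6.29 and TGFBI by 5.22, whereas POSTN was at -7.72. Each of these 4 was above the floor on 1 array only. Integrins and matrix receptors had a median of 1.13 and 17 of 28 at least 2-fold higher and 4 lower, with CD44 at 6.82, ITGA2 at 5.67, ITGA6 at 4.24 and ALCAM at -5.27. Extracellular proteases and inhibitors had a median of 0.67 and 15 of 33 at least 2-fold higher and 7 lower, with the plasminogen activator PLAU at 8.05, its receptor PLAUR at 5.59, TIMP1 at 4.62 and TFPI2 at -7.14. CD44, ITGA2, ALCAM and TFPI2 were above the floor on 1 array only as well. Averaged over all probe sets, LOXL2 was at 3.03, POSTN at -2.64, CD44 at 2.89 and ALCAM at -2.28, and TFPI2 was at -4.53 without probe sets ending in _x_at or _s_at. The protease median was 0.39 with the floor at the 60th percentile and the integrin median 0.75 under loess. TGF-beta and YAP targets had a median of 0.57, 8 of 27 at least 2-fold higher and 8 lower, and F3 at 6.50, TGFBI at 5.22, ID2 at -5.37 and CCN2 at -5.27, and this list lay inside the random range under 5 of 8 alternatives, with medians down to 0.20. The epithelial list was inside the range with a median of 0.59, although KRT18 was higher by 7.11 and KRT8 by 4.64.

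Hypoxia-inducible factor targets had a median of 1.02 in CL1-5 against CL1-0, with 15 of 29 at least 2-fold higher and 4 lower, the former including STC1 (6.20), NDRG1 (4.89), LOX (4.69) and EGLN3 (3.48). Genes of glycolysis had a median of 1.13 and 13 of 25 at least 2-fold higher and 3 lower, with ENO2 at 5.06 and PFKFB4 at 2.91, whereas the glucose transporter SLC2A3 was at -6.19 and PFKFB2 at -3.44, or -0.82 with the mean of all probe sets. Interferon-stimulated genes had a median of 1.36 and 23 of 37 at least 2-fold higher and 1 lower, with IFIT3 at 3.16, IFITM2 at 3.03, IFIT2 at 2.84 and ISG20 at 2.78. NF-kB targets and cytokines had a median of 1.03 and 13 of 25 at least 2-fold higher and 0 lower, with CXCL8 at 7.09, IL6 at 3.98, CXCL1 at 3.17 and NFKBIZ at 2.96. The tricarboxylic acid cycle list had a median of 0.35 and 6 of 26 at least 2-fold higher and 4 lower. Its largest ratios were those of enzymes next to the cycle, with ME1 at 4.54, PC at 3.18, PCK2 at -3.20 and IDH1 at -2.76. LOX, CXCL8, IL6, CXCL1 and ME1 were above the floor on 1 array only. ME1 was at 2.47 with the mean of all probe sets, and CXCL1 was at 1.89 and EGLN3 at 2.27 with the floor at the 60th percentile. The hypoxia and tricarboxylic acid cycle lists lay inside the random range without probe sets ending in _x_at or _s_at, at 0.33 and 0.15, and the NF-kB list did so with no floor, at 0.37. The interferon list had a median of 0.75 with the floor at the 60th percentile, and the heat shock list ranged from 0.42 to 1.29 over the alternatives, the latter with no rescaling and so with the shift of all genes in it. The heat shock list had a median of 0.42 and 2 of 12 at least 2-fold higher and 2 lower, with DNAJB1 at 1.05, DNAJA1 at 1.02, HSPB1 at -1.39, or -0.52 with no rescaling and the same shift, and HSPA4 at -1.26, the last reversing to 0.48 with the mean of all probe sets and to 0.22 without probe sets ending in _x_at or _s_at.

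Cytosolic ribosomal proteins were lower in CL1-5, with a median of -0.96, 13 of 32 at least 2-fold lower and RPL38 at -1.82, RPS23 and RPS12 at -1.36 and RPS7 at -1.34. That list lay inside the random range under quantile normalization (-0.22), loess (-0.24) and without probe sets ending in _x_at or _s_at (-0.50). It stayed below the range under the other 5 of 8 alternatives, among them no rescaling, where the shift of all genes put its median at -0.09, and the mean of all probe sets, where RPS23 reversed to 0.75, RPS12 was at -0.01 and RPL38 at -0.89. RPS7 was at -0.66 under quantile normalization. Immediate early genes had a median of -0.56, 6 of 26 at least 2-fold higher and 12 lower, with IER3 (5.86) and DUSP5 (5.75) higher and ATF3 (-5.64) and DUSP6 (-4.91) lower. Their list lay inside the range under 5 of 8 alternatives and stayed below it under 3. One of these 3 was no rescaling, where the shift of all genes put the median at 0.31, at percentile 1.59 of random lists.

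Over all 15946 genes measured in the comparison of the controls, 2726 were at least 2-fold higher in CL1-5 and 2256 at least 2-fold lower. The share of higher genes was 54.7%, but 42.9% under quantile normalization, 46.8% under loess and 90.4% with no rescaling. The median log2 ratio of all genes was 0.13, and -0.06, 0.03 and 0.83 under those settings in the same order. The naming rule ranked only genes above the floor on both arrays whose probe sets moved the same way. Besides genes named above, the highest under it were the protease PRSS23 at 7.30, IGFBP4 at 6.72, caveolin 1 (CAV1) at 6.61, TMEM158 at 6.56 and PRSS3 at 6.27. The lowest under it were osteopontin (SPP1) at -9.54, UPP1 at -6.60, BEX2 at -6.16, MYL9 at -5.89, PLTP at -5.72, ANXA1 at -5.32 and the stem cell factor SOX2 at -5.30. PRSS23 was at 4.74 with the mean of all probe sets, and MYL9 at -0.16 without probe sets ending in _x_at or _s_at. On the CL1-0 control array PLAU (7.82), F3 (7.63) and PRSS3 (7.24) had signals near the floor of 6.93. Over the alternatives their smallest ratios were 6.96, 5.37 and 5.06, and that of SPP1 was -6.57. The size of these ratios thus depends on the processing. The control arrays also differed in vector and in RNA and hybridisation controls, with a beta-actin 3' to 5' ratio of 6.04 in CL1-0 and 1.34 in CL1-5, and BioB signals of 761 and 104. Subline, vector and array preparation cannot be told apart here.

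**Figure D4:**
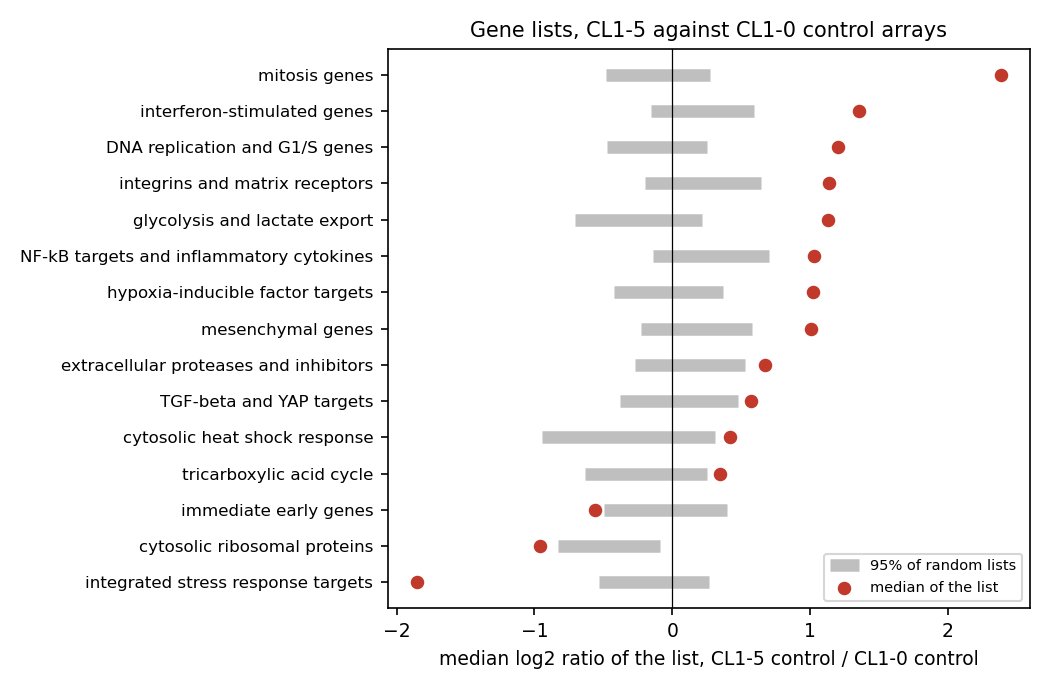
Median log2 ratio of the 15 gene lists outside the random range between the control arrays, CL1-5 over CL1-0. Red points are medians and grey bars span 95% of random lists. Mitosis genes stood highest at 2.38 and integrated stress response targets lowest at -1.85.

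Among the 7 lists of cell type markers, none lay outside the random range in the CL1-0 comparison or between the controls. In CL1-5 only the leukocyte list did, as given above. In CL1-0 the fibroblast list had a median of 0.10 over 7 genes, with CFD at 1.70. Between the controls, endothelial markers had a median of 1.04 over 8 genes and alveolar type II markers a median of -0.28 over 14 genes, with LAMP3, above the floor on 1 array only, at -4.92.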

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

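The tests of the AK4 level, of RNA degradation, of the list overlap and of the immediate early group were chosen after the results were seen, and the loess tests before.

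Mitosis genes stood at a median log2 ratio of 0.93 on the array labelled AK4 vector. Of random lists matched on level, 95% lay from -0.12 to 0.26, which argues against an intensity-dependent difference as the whole cause. After loess correction for level, the median was 0.88 against a random range of -0.18 to 0.19. Loess adds little here, because the random lists were already matched on level. More degraded RNA on the control array would make its 3' to 5' ratios higher. The 4 log2 differences of the actin and GAPDH ratios, AK4 vector minus control, ran from 0.11 to 0.30. Their median was 0.29, the opposite order. The dap spike-in control went the other way. Its 3' to 5' ratio was 8.58 on the control vector array and 6.03 on the array labelled AK4 vector. A difference in array preparation stays open. With AK4 shRNA in CL1-5 the mitosis genes had a median of 0.0047, inside the random range. Since AK4 probe sets showed no rise in CL1-0, the AK4 level cannot be told apart from other differences between these cultures. Growth state at harvest was not tested and stays open.

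Interferon-stimulated genes stood at a median of 0.58 with AK4 shRNA in CL1-5. The range of random lists matched on level was -0.06 to 0.09, which argues against an intensity-dependent difference as the whole cause. After loess the median was 0.57 against a range of -0.07 to 0.08, which adds little for the reason given above. On the array labelled AK4 vector the list's median was 0.084, inside a range of -0.10 to 0.26. An effect of AK4 loss may account for the pattern, and so may an antiviral response to the shRNA itself. These cannot be told apart, since the only AK4 shRNA group was set against 1 non-silencing group. More arrays of the same groups would not separate them.

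ATF3 was lower on the array labelled AK4 vector and higher with AK4 shRNA. Independent lists would share 0.115 genes of this kind and 1 was seen, too few to decide. If ATF3 moved with the immediate early genes as a group, they should be higher with AK4 shRNA. Without ATF3 their median there was 0.026 over 23 genes with an SD of 0.26, inside a range of -0.07 to 0.09, which argues against such a shift in both lines, while in CL1-0 it was -0.43 over 25 genes. An effect of AK4 on ATF3 stays open as a hypothesis, the CL1-0 value may belong to the lower immediate early genes there, and the CL1-5 signal lies near the floor.

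Probe sets outside the gene comparisons were also read. Among 5736 measured probe sets without a single gene symbol, 193 were at least 2-fold higher on the array labelled AK4 vector and 64 lower. The higher share was 3.36%, beside 3.21% of named genes. With AK4 shRNA, 3 of 6266 were higher and 6 lower. The lower share was 0.096%, beside 0.013% of named genes, and the higher share 0.048%, beside 0.091%. These differences rest on few probe sets and were not tested. Named genes were read from 1 probe set each, whereas every probe set without a single gene symbol was counted. The BioB control probe sets had a median log2 ratio of -1.38 in the vector comparison, and all hybridisation controls one of -1.25. Between the control arrays of CL1-5 and CL1-0 these medians were -2.96 and -2.56.

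CMPK2 was at 1.10 with the vector in CL1-0 and at 1.17 with shRNA in CL1-5, the same sign under opposite intended changes of AK4. The difference from the opposite signs that the design implies was not tested.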

How the results depend on the processing

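With 1 array per group no array could be left out and no other split made. No paired analysis was possible because each group is 1 array with no replicate number. The threshold of 1.5-fold was chosen after seeing the data. Signal over the floor limits dim genes such as ATF3 in CL1-5.

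Counts of genes moved with the threshold. At 3-fold, 65 genes were higher and 24 lower in the vector comparison, 0 and 0 in the shRNA comparison, and 1178 and 1027 between the controls. At 1.5-fold the counts were 1842 and 960, 133 and 80, and 4855 and 3702. With the mean of all probe sets, which dilutes the brightest one, 257 genes were higher with the vector, 6 higher and 1 lower with shRNA, and 1401 lower between the controls. Without probe sets ending in _x_at or _s_at, 1 gene was lower with shRNA. With no rescaling, 7185 genes were higher and 767 lower between the controls, which the differing array means produce. With the floor at the 60th percentile, which leaves fewer genes, 1741 were higher there.

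Genes lower with the vector and higher with shRNA numbered 0 under quantile normalization, the floor at the 60th percentile, 3-fold, the mean of all probe sets and without probe sets ending in _x_at or _s_at, and 3 at 1.5-fold. Genes with the mirror pattern numbered 1 at 1.5-fold. The correlation of both comparisons lay between 0.119 and 0.147.

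With no rescaling the immediate early median between the controls changed sign to 0.31. This setting raised the ratios of that comparison as a whole (median of all genes 0.83, from 0.13). The list stayed below its random range. Among genes, NDUFS7 with the vector was at -0.36 without probe sets ending in _x_at or _s_at. Between the controls HSPA4 was at 0.48 with the mean of all probe sets and at 0.22 without those probe sets, and RPS23 was at 0.75 with the mean. The cause of these gene reversals was not tested. Of 240 list medians under alternatives, 160 stayed within their spread, 79 moved with the sign kept, 14 of them between the controls with no rescaling, and 1 was the immediate early value above. Of 1500 values of genes, among them every gene given with a ratio in the text, 1294 stayed, 202 moved, 53 of them between the controls with no rescaling, and 4, all past 2-fold in the main setting, reversed. Another 2 of those that moved changed sign from a ratio under 2-fold, RAB20 with shRNA (0.09) and ATF6 with the vector (0.15), both with the mean of all probe sets. Of 24 ratios of AK4 probe sets, 20 stayed and 4 moved, all 4 between the controls with no rescaling. Loess was not run for single AK4 probe sets.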

Other observations

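At 1.5-fold, a threshold chosen after seeing the data, 34 genes were higher both on the array labelled AK4 vector and with AK4 shRNA. Independent lists would share 13.7. Lower in both were 7 genes, where independent lists would share 4.31. These expected counts assume no technical difference common to both pairs of arrays. In both lines the beta-actin 3' to 5' ratio was above that of the control, at 6.54 against 6.04 and 1.61 against 1.34. The dap spike-in ratio was lower in CL1-0, at 6.03 against 8.58, and higher in CL1-5, at 4.06 against 3.16. Whether these bear on the shared counts or on the correlation of both comparisons was not tested. Of the 34 genes higher in both, 5 belong to the interferon-stimulated list (BST2, HERC5, IFIT1, OASL and RIGI, named after their values were seen). The other 29 are not on it, CMPK2 among them. The 5 are therefore a count of list members and not of all genes that interferon may induce. Enrichment of the list among the 34 was not tested. RIGI was at 0.44 in CL1-0 without probe sets ending in _x_at or _s_at and at 0.48 in CL1-5 with the mean of all probe sets. Opposite directions gave 1 gene, ANKRD13D, at 0.97 with the vector and -0.59 with shRNA, or -0.16 there with the mean of all probe sets, and outside the naming rule, against 8.30 for independent lists, and 3 genes, ATF3, CCL5 and H4C8, the other way round against 7.11. H4C8, also outside the naming rule, belongs to a histone family of near-identical coding sequences and is uncertain. It was at 0.66 with shRNA and at 0.27 there with the mean of all probe sets.

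Metabolic and signalling lists gave further values inside the random range. In CL1-0, DNA replication and G1/S genes had a median log2 ratio of 0.22 over 40 genes, 5 of them at least 2-fold higher and 1 lower. The lower gene, CCND2, had the largest ratio of the list at -2.24, and UHRF1 was at 1.28, MCM4 at 1.15 and E2F8 at 1.10. MCM4 was at 0.64 with the mean of all probe sets and at 0.57 without probe sets ending in _x_at or _s_at. In CL1-5, cholesterol synthesis and uptake genes had a median of 0.12 with 17 of 19 above 0 with AK4 shRNA, and fatty acid genes one of 0.11 with 14 of 19 above 0. Kinases of adenylate and other nucleoside phosphates had a median of -0.02 in CL1-5, where AK4 and CMPK2 were the members past 2-fold. Between the controls, p53 targets had a median of 0.17 and a mean of -0.36, with GDF15, above the floor on 1 array only, at -4.82 and SESN2 at -3.06. GDF15 was at -1.83 with the mean of all probe sets and at -0.97 without probe sets ending in _x_at or _s_at.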
